A study of Homo sapiens with 4 samples.

How the data were processed

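Total RNA of 4 samples of MIA PaCa-2, an established human pancreatic cancer cell line, was measured on 1-colour expression microarrays. Per the labels, cells were transfected with a precursor of the microRNA miR-193b or with a negative control precursor at 30 nM, and RNA was taken after 48 h. Each group held 2 samples, numbered 1 and 2 in the labels. The labels did not say that the samples came from separate cultures, so p-values measured only the spread between these samples, which may be technical.

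Per the file headers, the deposited scanner files held fluorescence intensity values made with Agilent Feature Extraction 10.5.1.1 on 1 Cy3 channel, from arrays of 60-base probes placed on genome build hg18. Per the file headers, the authors' processed intensity of each spot had been background-subtracted and detrended within its array, with an error-based surrogate where the signal was not above background. These intensities had not been scaled between arrays. All 4 arrays shared 1 slide and 1 scan, so no slide or scan term could be fitted. A second deposited table held the authors' log2 normalized values, which were centred on the mean of the control arrays, and the authors' fold change of treated over control cells. The steps of that normalization were not given in the sources used here. The log2 scale, the centring and the direction were checked against the scanner values, and 99.8% of its unnormalized values on each array lay within 1% of them. The medians of the authors' normalized columns were -0.02 and 0.07 for the miR-193b arrays and 0.01 and -0.01 for the control arrays.

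Each array carried 45015 spots, of which 1639 were control spots and 43376 were gene spots of 41000 probes. No gene spot was saturated, and between 87 and 126 gene spots per array were marked as outliers and left out. Gene spots well above background numbered 27161 and 27330 on the miR-193b arrays and 27934 and 28624 on the control arrays. The number of arrays limited the precision.

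From the scanner files, the log2 processed intensity was taken minus the 75th percentile of its array, and spots of 1 probe were averaged. Probes were kept where they were well above background on both arrays of at least 1 group, which left 25932 probes. Each gene was represented by its probe with the highest mean over the 4 arrays, giving 18924 genes or transcripts. Of 593 called genes with a second probe above background, 541 moved the same way on it. Gene names in the files were those of the array design. They were updated through a RefSeq gene table (assembly GRCh38.p14), by accession for 24794 probes, by gene number for 4305, by symbol for 307 and by synonym for 170. The file's name was kept for 11424 probes, and 13719 of the tested genes had a current symbol. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are the miR-193b group minus the control group, with the standard error (SE) of the fit.

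A gene not well above background on any array of a group had only a bound there. Its change was given as at least N-fold, the mean of the brighter group against the mean, per array of the dim group, of the higher of the gene's own value and the lowest signal well above background. The genes named were fixed before the data were examined. They were the 12 largest falls and the 12 largest rises among symbols that passed the test, were separated between groups and were well above background on both arrays of the higher group. To these were added every measured member of a list of reported miR-193b targets and up to 4 members of each other list, those with the smallest p. Some genes that this rule takes are not reported here by name, and they stay in all counts and tests but not in the plot of reported targets or the gene rows of the sensitivity table. Genes named outside this rule are said to have been chosen after their values were seen.

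The 19 gene lists, fixed before the data were examined, covered reported miR-193b targets, RAS-MAPK components, ERK output, G1/S and replication, G2/M and mitosis, p53 response, the BCL2 family, the urokinase system, epithelial and mesenchymal markers and interferon response. The others were stress response, serine metabolism, hypoxia, cholesterol, the small RNA pathway, ribosomal proteins and markers of other cell types. They were tested with camera at a preset correlation of 0.01 between genes, which compares a list with the other genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The former takes its p from the residual degrees of freedom of these few arrays and so has little power. A call lost with it therefore does not show that correlation between genes made the shift. Fry's p tests whether a list's genes move, on balance, one way, without comparison with other genes.

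Alternatives covered the background correction (normexp with an offset of 50), quantile and median scaling, the authors' normalized values, the filter on dim probes, outlier spots, the mean of a gene's probes, a variance trend, the replicate number as a block, 2-fold criteria and each array left out. The search for seed sites in transcripts that was fixed in advance was not run, because transcript sequences were not used here. The fit was tested on simulated data with the spread of these arrays and 18924 genes, in 20 simulations each. With 2000 changed genes, 79.4% of those set to a log2 change of 1 and 97.0% of those set to 2 were recovered, with a mean of 61.8 false calls. With 200 changed genes, 1.19% and 72.1% were recovered. Of genes set to a log2 change of 0.585, 26.3% were recovered with 2000 changed genes and 0% with 200. A gene that did not pass may therefore still have changed by such an amount. Further calculations used Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1.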

Results

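The study set out to find genes targeted by miR-193b, a microRNA, by raising its level in MIA PaCa-2 cells and measuring transcripts genome-wide. Expression was measured on 4 arrays, 2 from cells given the miR-193b precursor and 2 from cells given the negative control precursor, at 48 h. Between 27161 and 28624 gene spots per array were well above background. Across the genes tested, Pearson's r between arrays was 0.993 and 0.994 within groups and 0.979 to 0.986 between groups, over genes that are not independent replicates. The median SD of a gene between replicates was 0.114 (log2) in the miR-193b group and 0.0944 in the control group.

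Cells given the miR-193b precursor had lower transcript levels of the urokinase PLAU, of its receptor PLAUR and of many cell cycle genes than cells given the control precursor. Of 40 genes of DNA replication 24 were lowered, and of 35 of mitosis 22, with none raised and list medians of -0.71 and -0.65 (log2). Both lists were lower than the other genes with camera, but not with an estimated correlation (adjusted p = 0.868 with an estimated correlation for each). PLAU and PLAUR fell 3.68-fold and 3.38-fold. The ectonucleotidase NT5E fell 3.85-fold and the G1 cyclin CCND1 2.49-fold on their brightest probes, with log2 changes of -1.17 and -0.96 on the other NT5E probes and of -1.66 and -0.79 on the other CCND1 probes. The anti-proliferative gene BTG2 rose 4.40-fold, and the flagellar genes RSPH1 and CFAP206 were among the largest rises. With limma, 1083 genes were raised and 914 were lowered at an adjusted p under 0.05, and 401 of the raised and 198 of the lowered genes moved by 2-fold or more (213 and 94 with normexp background correction).

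Among the 12 largest falls, the genes bright in both groups included NCEH1, NT5E, PLAU, ADAMTS4, CARD10 and PLAUR. NCEH1, a hydrolase of cholesteryl esters, fell by 2.04 (SE 0.16, adjusted p = 0.0246, n = 2 per group, limma). Its level relative to the array's 75th percentile was 2.69 ± 0.26 (SD, n = 2) in control cells and 0.65 ± 0.05 (SD, n = 2) in miR-193b cells. The NT5E probe lay on chromosome 6, from 86261610 to 86261669 (hg18), and its level went from 3.52 ± 0.19 to 1.57 ± 0.23 (SD, n = 2 each). PLAU, probed on chromosome 10 from 75347056 to 75347115 (hg18), went from 5.38 ± 0.34 to 3.51 ± 0.31 (SD, n = 2 each). CARD10, a scaffold protein of NF-kappa-B signalling, fell by 1.77 (SE 0.17), and the aggrecan-cleaving protease ADAMTS4 fell by 1.83 (SE 0.35).

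Others of these falls were not well above background on either miR-193b array, so only a bound was available. FAM216B was at least 2.92-fold lower, SIPA1L2 at least 2.82-fold, the long non-coding RNA LINC00474 at least 2.16-fold and the Toll-like receptor gene TLR6 at least 1.59-fold (adjusted p = 0.0246 each, limma). With normexp background correction TLR6 did not pass (adjusted p = 0.057). In all, 70 lowered genes were not well above background on the miR-193b arrays.

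The rises were led by genes dim or below background in control cells. CFAP206, a cilia and flagella associated gene, was probed on chromosome 6 from 88230777 to 88230836 (hg18). On this probe CFAP206 was at least 12.5-fold higher, and CFAP70 was at least 7.86-fold higher (adjusted p = 0.0246 each, limma). A second, dimmer CFAP206 probe gave a smaller log2 change of 3.43, with no bound applied. RSPH1, a radial spoke component of motile cilia, rose by 3.48 (SE 0.52, adjusted p = 0.0325) and was well above background on all 4 arrays. FER1L4, a non-coding transcript, rose by 3.46 (SE 0.30), from -1.95 ± 0.23 to 1.51 ± 0.58 (SD, n = 2 each). TLL2 was at least 7.04-fold higher, the sulfotransferase CHST6 at least 6.51-fold, NTN5 at least 5.78-fold, ARMH1 at least 4.41-fold and ZNF804B at least 2.51-fold. LDHD, a mitochondrial D-lactate dehydrogenase, rose by 2.47 (SE 0.26). YPEL2 rose by 2.66 (SE 0.36) and ABAT, the GABA transaminase, by 3.39 (SE 0.58), and each was well above background on 1 of the 2 control arrays. The second probe of ABAT gave 1.14, and with the mean of its probes ABAT did not pass (adjusted p = 0.0517). In all, 54 raised genes were not well above background in controls.

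Of 30 genes earlier reported as miR-193b targets, 27 were tested, and 15 fell, none rose and 12 did not pass (median log2 change -0.98). Adjusted over the list alone, 23 fell and 1 rose. Some members may have been reported from experiments of this kind or from these very samples, so the list is not independent evidence of its direction. Those that fell included NT5E, PLAU, ETS1, SHMT2, STARD7, ARHGAP19, STMN1, CCND1, YWHAZ, CRKL, UHRF1, IL17RD, TGFBR3 and MAX. The microtubule-destabilizing protein gene STMN1 fell by 1.43 (SE 0.11, adjusted p = 0.0246), and the transcription factor ETS1 fell by 1.65 (SE 0.15, adjusted p = 0.0246). Dimmer probes of ETS1 gave -1.69 and -0.79. MAX, the partner of MYC, fell by 0.85 (SE 0.15, adjusted p = 0.0405), although not with the mean of its probes (adjusted p = 0.12). CDK6, a G1 cyclin-dependent kinase, had a log2 change of -1.64 (SE 0.34) that missed the threshold (adjusted p = 0.0506). The anti-apoptotic gene MCL1 was at -0.48 (SE 0.14), and the others not passing lay between -0.90 for TNFRSF21 and 0.46 for RAB22A. They were PTK2 (-0.49), SOS2 (-0.46), SMAD3 (-0.43), SRSF2 (-0.42), RPS6KB2 (-0.38), ESR1 (-0.37), HIC2 (-0.07) and DNAJC13 (0.01). A second, dimmer probe of RAB22A gave -0.54. The second probe of SMAD3, of nearly the same brightness, gave -0.70. Dimmer probes gave -0.57 and -0.68 for MCL1, -0.29 and -0.54 for PTK2 and -0.07 for HIC2. The list was lower than the other genes (camera, adjusted p = 2.4e-11), but not with an estimated correlation (adjusted p = 0.868 with an estimated correlation).

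**Figure D1:**
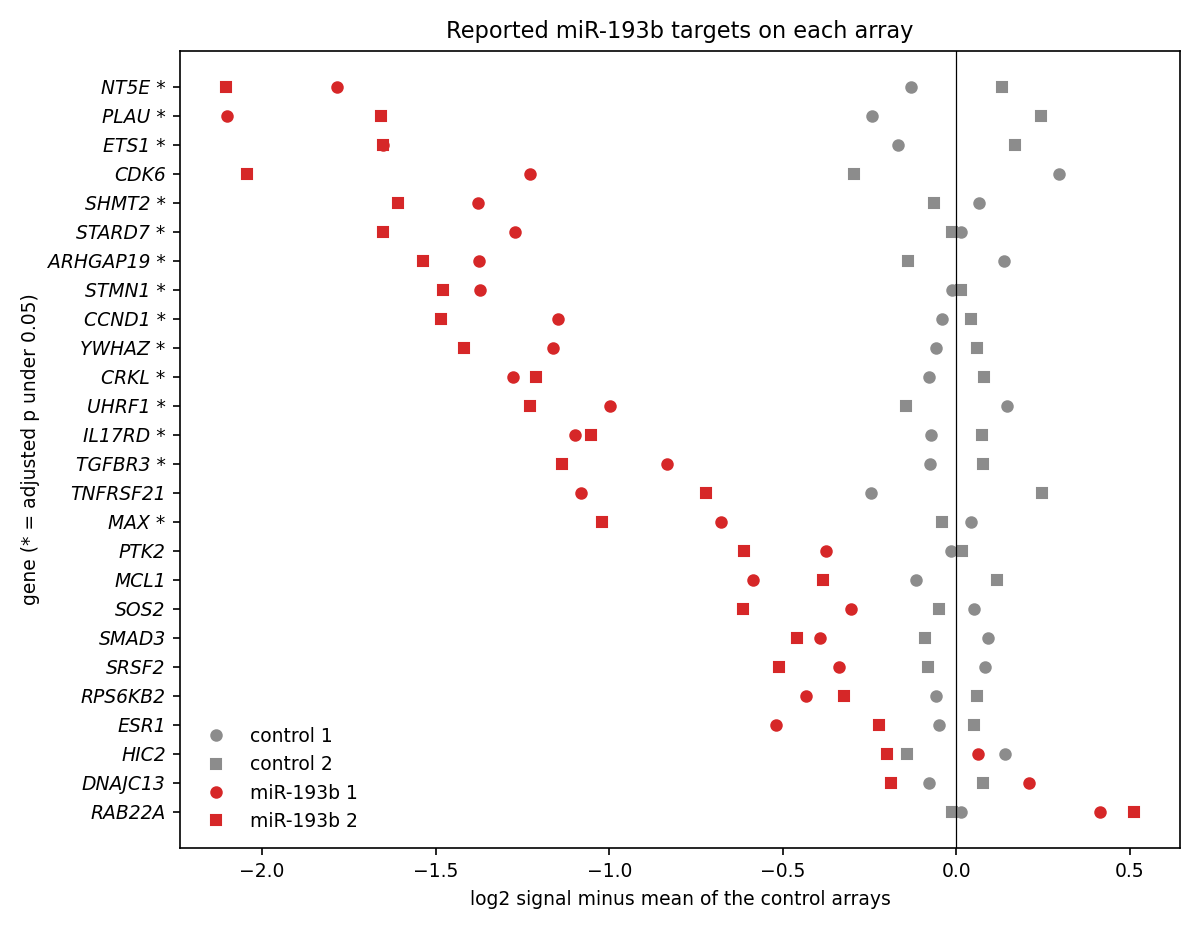
Log2 signal of 26 of the tested reported targets on each array (horizontal axis, relative to the mean of the 2 control arrays), with 1 row per gene, red symbols for the miR-193b arrays, grey symbols for the control arrays, circles for replicate 1 and squares for replicate 2. The 14 genes marked with an asterisk passed an adjusted p under 0.05, and RAB22A lay above the controls on both miR-193b arrays, with a log2 change of 0.46.

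Of 35 components of the RAS-MAPK cascade, 3 fell, none rose and 32 did not pass, with the same counts lowered and raised adjusted over the list alone. Those that fell included the 14-3-3 protein gene YWHAZ (-1.29, SE 0.14) and the adaptor gene CRKL (-1.24, SE 0.11), both also in the list of reported targets. A dimmer probe of CRKL gave -0.65. The kinase gene MAPK3 was at 0.51 (SE 0.11, adjusted p = 0.055). The list as a whole did not shift (median -0.05, camera, adjusted p = 0.66). Of 25 genes that ERK signalling induces, 8 fell, none rose and 17 did not pass, and adjusted over the list alone 14 fell and none rose. The AP-1 subunit gene FOSL1 fell by 1.49 (SE 0.13), the growth factor gene HBEGF by 1.37 (SE 0.14) and the ETS factor gene ETV4 by 1.20 (SE 0.12). The median of this list was -0.50 and it was lower than the other genes (camera, adjusted p = 8.6e-06), but not with an estimated correlation (adjusted p = 0.868 with an estimated correlation).

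Of 40 genes of G1/S and DNA replication, 24 fell, none rose and 16 did not pass, and adjusted over the list alone 37 fell and none rose. DTL, which targets the licensing factor CDT1 for degradation, fell by 1.16 (SE 0.15), the ribonucleotide reductase subunit gene RRM2 by 0.92 (SE 0.11) and the helicase subunit gene GINS3 by 0.85 (SE 0.10), and the helicase factor gene CDC45 fell 1.99-fold. Of 35 genes of G2/M and mitosis, 22 fell, none rose and 13 did not pass, and adjusted over the list alone all 35 fell. The kinesin gene KIF2C fell by 0.96 (SE 0.12), the mitotic kinase gene PLK1 by 0.85 (SE 0.10), the centromere histone gene CENPA by 0.82 (SE 0.12) and the cytokinesis gene ECT2 by 0.81 (SE 0.10). Both lists were lower than the other genes (camera, adjusted p = 2.4e-15 each), but not with an estimated correlation (adjusted p = 0.868 with an estimated correlation for each). Relative to the control mean, the median member of the replication list was at -0.65 and -0.83 (log2) on the 2 miR-193b arrays, and that of the mitosis list at -0.55 and -0.77. Each control array lay within 0.06 of that mean for both lists.

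Of 24 p53 response genes, 3 rose, 1 fell and 20 did not pass, and adjusted over the list alone 5 rose and 3 fell. BTG2 rose by 2.14 (SE 0.21), TP53INP1, an autophagy and stress gene, by 1.82 (SE 0.24) and TP53I3 by 0.56 (SE 0.10), while AEN, a nuclease gene, fell by 0.59 (SE 0.12). Of 16 BCL2 family genes, BMF rose, BCL2L1 fell and 14 did not pass, and adjusted over the list alone 2 rose and 2 fell. BMF, which promotes cell death, was at least 2.32-fold higher, since it was not well above background in controls, and BCL2L1, which encodes the survival protein BCL-XL, fell by 0.76 (SE 0.10). PMAIP1 was at a level 2.15-fold below control but did not pass (adjusted p = 0.059), and BAD was at 0.46 (SE 0.11). Neither list shifted as a whole (camera, adjusted p = 0.955 each).

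Of 17 tested genes of the urokinase system, proteases and invasion, 3 fell and 14 did not pass, and the count was also 3 adjusted over the list alone. These included PLAU and PLAUR, the enzyme and its receptor, while the gelatinase gene MMP9 was at -0.41 (SE 0.11). Relative to the control mean, the list median was -0.02 and 0.24 on the 2 miR-193b arrays, and camera called no shift (adjusted p = 0.955), with a direction that turned in 2 of the 4 fits with 1 array left out. Of 18 genes of serine and one-carbon metabolism, 5 fell and 13 did not pass, and adjusted over the list alone 6 fell and 2 rose. The mitochondrial enzyme gene SHMT2 and the glycine cleavage gene GLDC each fell by 1.49 (SE 0.13 and 0.20), TYMS fell by 0.88, GART by 0.59 and MTHFD2, named after its value was seen, by 0.60. With median scaling GART did not pass (adjusted p = 0.0545). The list median was -0.18 (camera, adjusted p = 0.25).

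Of 21 genes of cholesterol synthesis and uptake, 1 rose, 2 fell and 18 did not pass, and adjusted over the list alone 3 rose and 4 fell. HMGCS1, an enzyme of the mevalonate pathway, rose by 0.57 (SE 0.12). The median was 0.07 and camera called no shift (adjusted p = 0.955). Of 21 hypoxia and glycolysis genes, 3 fell and 18 did not pass, and adjusted over the list alone 3 rose and 3 fell (camera, adjusted p = 0.92). The hexokinase gene HK2 fell by 0.97 (SE 0.11) and VEGFA by 0.56 (SE 0.10), the latter not with normexp, median scaling or the mean of probes (adjusted p = 0.0775, 0.0522 and 0.0563), and PFKFB4 was at 0.45 (SE 0.11). BNIP3 had a log2 change of -0.54, passed on a probe well above background on 1 of the 2 miR-193b arrays and did not pass with normexp, quantile scaling or a variance trend (adjusted p = 0.622, 0.0515 and 0.135). Of 23 genes of the unfolded protein and amino acid stress response, DDIT4 and SEL1L rose by 0.88 and 0.67, SLC3A2 fell by 0.65 and 20 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.941). HERPUD1 of this list was at 0.41. SLC3A2 did not pass with median scaling or the mean of probes (adjusted p = 0.0555 and 0.0578).

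Of 25 interferon response genes, IFITM1, IFI35 and IRF9 rose by 1.47, 1.03 and 0.56 and 22 did not pass, with 3 raised also adjusted over the list alone, and USP18 was at -0.42. Relative to the control mean, the list median was -0.34 on 1 miR-193b array and 0.06 on the other, and camera called no shift (adjusted p = 0.955). IRF9 did not pass with median scaling or the mean of probes (adjusted p = 0.0582 and 0.108). Of 16 small RNA pathway genes, TNRC6B, a partner of Argonaute, rose by 0.97 (SE 0.13), and 15 did not pass. Among these were AGO2 (-0.57), DGCR8 (-0.45) and DICER1 (0.51). Second, dimmer probes gave 0.03 for DICER1 and -0.44 for DGCR8, and the other TNRC6B probes gave 0.37, 0.96 and 0.98. Adjusted over the list alone 1 rose, and the median was -0.04 with no shift called (camera, adjusted p = 0.955). None of 32 ribosomal protein genes passed, over all genes or adjusted over the list alone, and their median was 0.07 (camera, adjusted p = 0.18). RPL30, RPS9, RPS13 and RPL11 were at 0.26, 0.25, 0.21 and 0.20.

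Of 13 tested epithelial markers, the junction gene JUP rose by 1.39 (SE 0.27) and 12 did not pass, among them MUC1 (2.15-fold above control, adjusted p = 0.068), TJP1 (0.30) and OCLN (-0.32), and none passed adjusted over the list alone. Relative to the control mean, the list median was -0.20 on 1 miR-193b array and 0.35 on the other, and camera called no shift (adjusted p = 0.955). Of 12 mesenchymal markers, the collagen gene COL6A1 rose by 1.40 (SE 0.14), the receptor kinase gene AXL fell by 0.89 (SE 0.15) and 10 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.955). COL5A1 did not pass (adjusted p = 0.0948), and TWIST1 was at -0.39. Of 8 pancreatic acinar and endocrine markers, RBPJL was at least 1.82-fold lower (adjusted p = 0.0337) but did not pass with normexp (adjusted p = 0.188), and 7 did not pass, among them CEL (-0.33), PTF1A (-0.22) and CHGA (-0.16). Adjusted over the list alone 1 fell (camera, adjusted p = 0.25). None of 6 stromal, endothelial and blood cell markers passed in either way (camera, adjusted p = 0.955), and COL1A2, CD14 and CD68 were at 0.79, 0.22 and -0.52, with MS4A1 not well above background on either miR-193b array.

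**Figure D2:**
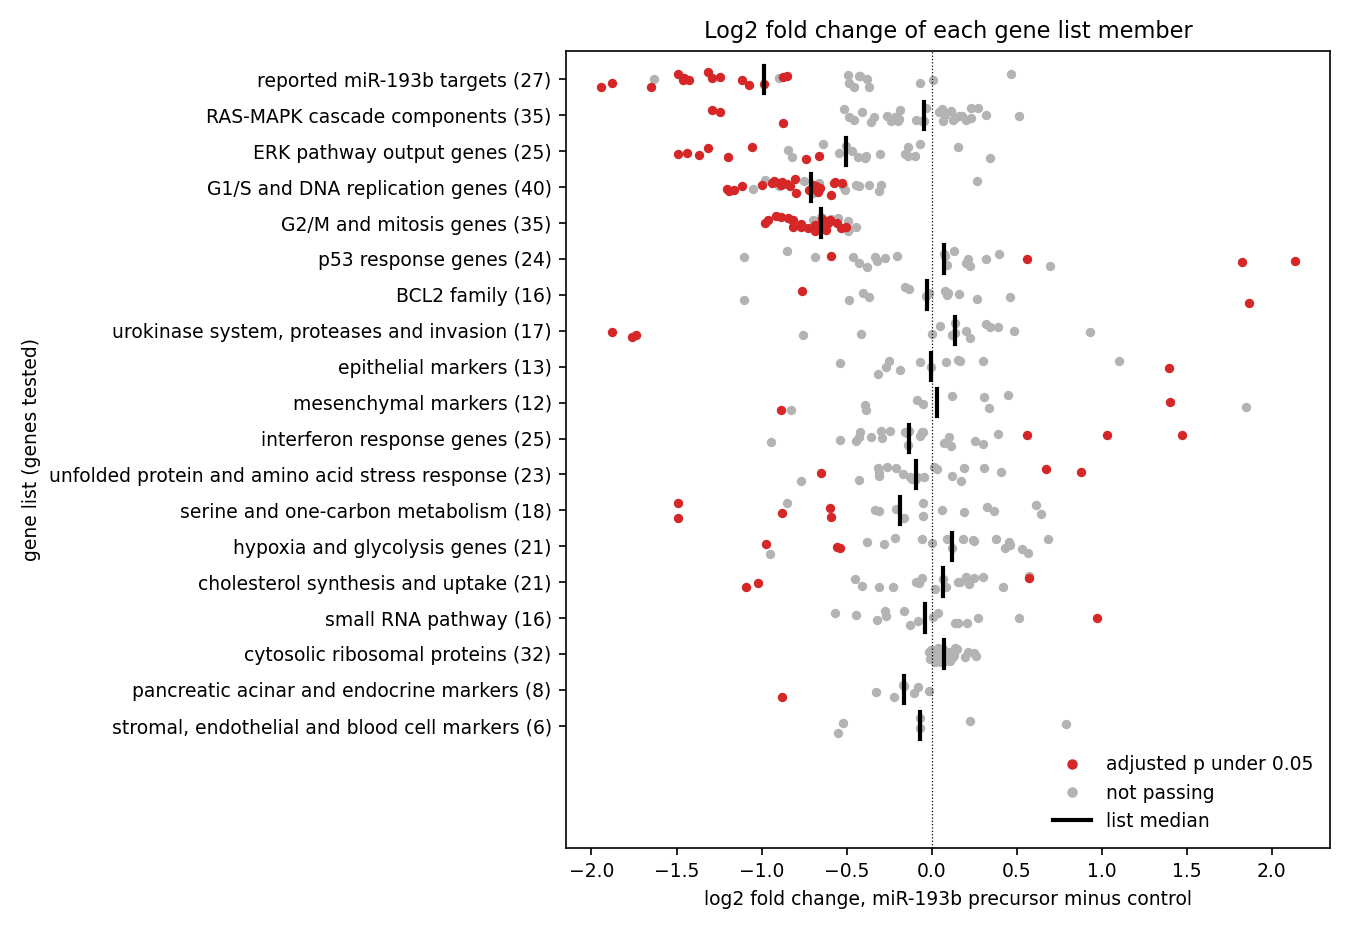
Log2 fold change (miR-193b precursor minus control, horizontal axis) of each tested member of the 19 gene lists, with 1 point per gene, red where the adjusted p was under 0.05 and grey otherwise, and a black bar at the list median. The lists of reported targets, ERK output, replication and mitosis have medians of -0.98, -0.50, -0.71 and -0.65, and the ribosomal protein genes lie in a narrow band around 0.07.

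The authors' deposited table listed 1110 probes at 2-fold or more up and 967 at 2-fold or more down, over all probes and with no test. The calls rested on all 4 arrays: with any 1 array left out, limma called 0 genes, or 1 without the second miR-193b array, while 3706 to 5420 genes had an unadjusted p under 0.05 (5923 with all arrays, 946.2 expected by chance). With no filter on dim probes, limma called 0 of 30058 genes, with 5769 at an unadjusted p under 0.05.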

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

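Synthetic control transcripts added to the RNA were not used in the comparisons. One of the 10, read by 32 spots per array, was 2.02 (log2) higher on the second miR-193b array than the mean of the control arrays. It was noted because it is a signal outside the main measurement that exceeded the control samples. The other 19 values on the miR-193b arrays lay between -0.60 and 0.26 of that mean, and the test on this was chosen after the values were seen. Most of these values were above the mean, and those of the brighter transcripts lay 0.06 to 0.17 above it. The cause of this offset was not tested.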

How the results depend on the processing

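No test in this part was chosen after the results were seen. The 1997 genes called with limma became 3123 (1644 raised, 1479 lowered) with a variance trend. They became 599 (401 raised, 198 lowered) with a 2-fold minimum added (213 raised and 94 lowered with normexp), and 515 (362 raised, 153 lowered) with 2-fold in both same-numbered comparisons and no p-value, both stricter by construction. With no filter on dim probes 0 were changed, 0 raised and 0 lowered (5769 at an unadjusted p under 0.05, smallest adjusted p 0.131), among 30058 genes, and the cause was not tested. Leaving out 1 array gave 0 to 1 changed, 0 to 1 raised and 0 to 0 lowered (limma, 3706 to 5420 at an unadjusted p under 0.05), with 1 residual degree of freedom, the lone sample being assumed to vary like the other group. None of the 1997 genes changed sign there, which is no support, since they were chosen on the same arrays. Other scalings, normexp, the authors' values, a stricter filter, outlier spots kept and the mean of probes gave 1860 to 2348 calls, of which 1608 to 1997 were shared.

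The samples shared only a number. Deviations of same-numbered samples from their group means had a correlation of 0.41 across genes, and the replicate number as a block raised the count to 4295 (2159 raised, 2136 lowered). The 4 called lists stayed 4 with the block, normexp, quantile scaling and no filter, were 4 to 5 with 1 array left out, and were 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.0749). A slide or scan block and the seed-site alternatives were not run. Signal over background limits the dim genes: 54 raised and 70 lowered genes have only a bound in the dimmer group.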

Other observations

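The gene annotation terms with and without list members, camera on the peroxisome genes, the matched lists for replication and mitosis, the check of 1 array and the check of base composition were tests chosen after the results were seen, and the genes named in this section were chosen after their values were seen. The percentile tests of the motile cilia list and of the seed words were fixed before their values were seen. Whether camera on these genes and Fisher's test were also fixed then was not recorded. Of 751 annotation terms, 24 were enriched among lowered genes and 1 among raised genes (hypergeometric, Benjamini-Hochberg per direction, 11390 annotated genes as background, genes taken as independent). Many of the 24, such as cell cycle, mitosis and DNA replication, drew on the fixed lists, and without members of those lists 7 were left. Cell cycle (39 lowered genes of 339, hypergeometric, adjusted p = 0.00056), cell division and mitosis were still among the 7, but DNA replication was not. DNA repair, also among the 7, held 20 lowered genes of 126 where 6.25 were expected (adjusted p = 0.00088). These included BLM, FANCD2, EXO1 and CHEK1. FANCD2 and CHEK1 were also lowered members of the cell cycle term, so DNA repair is not a separate theme. Peroxisome was the term among raised genes, with 14 of 72 genes raised, 3 lowered and 4.22 raised expected (adjusted p = 0.046). Tested together, the 72 genes had a median of 0.19 and were higher than the other genes (camera, adjusted p = 0.0023). With an estimated correlation they were not (camera, adjusted p = 0.165 with an estimated correlation). The term was picked from these same data, so neither result is independent of that choice. The raised genes included catalase (CAT, 1.14, SE 0.18), the epoxide hydrolase EPHX2 (1.34, SE 0.15), the thiolase ACAA1 (0.72, SE 0.11) and the biogenesis factors PEX6 (0.68) and PEX11G (1.04).

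Genes of motile cilia formed another group with raised members. Besides RSPH1, CFAP206 and CFAP70, a list of 165 genes was tested. It left out the cilia genes seen among the largest changes, which included a large fall as well as rises. Of its 77 tested members, 23 rose, 3 fell and 51 did not pass, and adjusted over the list alone 39 rose and 4 fell. The list was higher than the other genes (camera, adjusted p = 1.2e-07), but not with an estimated correlation (adjusted p = 0.184 with an estimated correlation). SPAG8 was at least 1.73-fold higher, and NME5 (1.85, SE 0.18), RIBC1 (1.83, SE 0.18), the dynein heavy chain gene DNAH7 (1.75, SE 0.18) and the assembly factor gene DNAAF3 (1.38, SE 0.12) rose. DNAH11, CFAP45 and DNAH14 fell by 0.95, 0.94 and 0.53. FOXJ1, a master regulator of motile cilia, was at -0.45 (SE 0.24, adjusted p = 0.268).

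For the cilia rise, 2 technical explanations were weighed. Selection of a few extreme genes is argued against, since the median of the unselected list was 0.50, at percentile 100 of 10000 random lists matched on signal and GC content (highest 0.14). Signal near background as the whole reason is argued against, since the 66 members well above background on all 4 arrays had a median of 0.49, also at percentile 100. Some of these members were still dim, such as DNAH7 at a control level of -4.34. With normexp the median of the whole list was only 0.29, so the size of the rise depended in part on background correction. That value was not set against random lists. The replication and mitosis medians were -0.70 and -0.66 with normexp, close to those of the main fit. The random lists ignore correlation between genes, which stays open as a reason for too small a spread. A programme of cilia genes released by the precursor is a hypothesis that may fit these values, with FOXJ1 not raised and no protein or cilia measured.

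For the fall of replication and mitosis genes, probe GC content or signal level is argued against, since the median of both lists together was -0.69 and the lowest of 10000 matched random lists was -0.24. These random lists also ignore correlation between genes, estimated at 0.50 in the replication list and 0.63 in the mitosis list. Their spread may therefore be too small. One deviating array is argued against, since the median on the miR-193b array nearer the controls was -0.60 and the control arrays lay at 0.04 and -0.04. Slower cycling of the precursor-treated cells, with lower CCND1 and higher BTG2, may account for the pattern. Growth was not measured in these files, and a general effect of this precursor on cell health stays open.

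For the lowered genes as a whole, direct pairing with miR-193b was tested in the 60-base probe sequences, a small part of each transcript. The seed match GGCCAGT of the 3p strand was in the probes of 59 genes, of which 10 were lowered and 4 raised (lowered, 16.9% against 4.83% of all genes, Fisher's exact test, two-sided, genes taken as independent, p = 0.000479), and the lowered included PLAU, GART, MARCKSL1 and ACTN4. These genes were lower than the others (camera, adjusted p = 0.0229), but not with an estimated correlation (adjusted p = 0.165 with an estimated correlation). The median change of the word stood at percentile 0.843 of 11388 words, counting only words in the probes of at least 30 genes. Under the same limit it was the lowest of 142 words made of the same 7 bases (percentile 0.704 among them). This argues against base composition. The seed match AAACCCC of the 5p strand, in the probes of 71 genes, stood at percentile 26.9, so no 5p shift was seen there. A weak effect, or one through sites elsewhere in the transcripts, could not be seen this way. The values of GGCCAGT may fit loss of transcripts that pair with the 3p seed as a part of the change. Their median was -0.15 against -0.02 for genes without the word. Most lowered genes had no such word in their probe, and whether their transcripts hold one elsewhere stays open.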
